A study of Caenorhabditis elegans with 2 samples.

How the data were processed

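Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans embryos of mixed stage, with an age label of 2 hours, from strain OP702. This strain lacks a working unc-119 gene of its own and carries a transgene made of flh-1 fused to GFP and FLAG tags together with a rescuing copy of unc-119. Chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. The antibody entry of each sample reads flh-1, the tagged protein. The 2 samples are biological replicates 1 and 2 of 1 group, so no comparison between groups was possible, and every result below describes peak positions within this group.

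Relaxed peak lists of 30000 entries were deposited for each replicate and for the pooled reads of both, together with the optimal set of peaks left by the threshold of the irreproducible discovery rate (IDR) procedure, which compares peak ranks between replicates. Each list was made from alignments to the ce11 assembly against a control alignment, per the description files deposited with the samples. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each entry was computed by the authors' peak caller, and it was used only to rank and describe entries within a list. The deposited lists also hold a −log10 q value, which reached a shared ceiling of 1.57 at all 371 optimal peaks and was therefore not used for ranking. The lists hold no read counts, so the depth of the libraries is unknown and no interval or floor that depends on depth is given. No mock precipitation or untagged strain was analysed here.

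Positions are given in ce11 (WBcel235), counted from 1. Genes came from the Ensembl annotation of that assembly, and symbols from the RefSeq annotation joined on the WormBase identifier, which matched 46881 of 46926 genes. Location tests used the 364 optimal peaks on nuclear chromosomes. The background was the 29384 pooled entries whose summit lay more than 1000 bp from every nuclear optimal summit. A promoter ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene, and a gene with a summit in that window was called bound. Shares carry exact (Clopper-Pearson) 95% intervals, which treat peaks as independent and cover no variation between embryo batches.

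Promoter share, non-coding gene lists and GC content were set against 10000 random draws of background summits with the same number on each chromosome, as two-sided permutation tests whose smallest p is 2.0e-04. Chromosome shares were compared with the background by exact binomial tests, adjusted over 6 chromosomes. The 27 protein-coding lists were tested by Fisher's exact test against all other protein-coding genes among 19973, and the 8 non-coding lists by draws, each family with Benjamini-Hochberg adjustment. Words of 6 bp were counted in the window reaching 50 bp to each side of the summit. Background summits were matched on chromosome, promoter status and GC content in bins of 5 percentage points, at 10 per peak where a bin held that many, which gave 3524. The peaks' own flanks, used as an alternative background, were not matched on GC content. Words were named on chromosomes I, III and V, and the 5 words with the lowest p were then tested on II, IV and X. Replicate agreement was the share of the 371 strongest entries of one replicate with a summit within 100 bp of one of the 371 strongest of the other. Chance came from 1000 circular shifts along each chromosome, whose smallest p is 0.001. Shifts shorter than 1000 bp were excluded after it was seen that a near-zero shift left one list almost in place.

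The tests, gene lists, 9 of the words and most alternative settings were fixed before the data were examined. The class of peaks with a summit within 100 bp of a tRNA or snoRNA gene, the results without those peaks, the place of the summit against those genes and the comparison of tRNA isotypes were chosen after seeing the data. Named genes followed a rule fixed in advance: the nearest protein-coding or microRNA gene at the 20 strongest peaks, up to 6 bound members of each list, and flh-1, unc-119, flh-2, flh-3, peb-1, lin-4, mir-48 and mir-241. Because that rule gave more than 30 names, part of them is given as counts. The genes let-7, mir-84 and sls-2.1, and the genes whose introns hold tRNA or snoRNA sites, were named outside the rule, after their values were seen. The alternatives were a stricter peak set, each replicate alone, other promoter windows and 5′ ends, other backgrounds, other overlap limits and other word windows.

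The tests were run on simulated data first. With no effect planted, 2.50% of 200 simulated sets of 364 summits passed the promoter test, 4.50% passed the GC test, and 1.50% of 200 simulated gene sets gave any protein-coding list. These gene sets were drawn gene by gene and not from summits. They therefore do not test how genes that share a summit, or uneven scoring of positions, affect the list test. A word planted in 20% of windows ranked at the top in 5 of 5 runs of 364 summits, and a planted agreement of 60% between lists of 371 entries was estimated at 59.7%. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.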

Results

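FLH-1 is a DNA-binding protein with a FLYWCH zinc finger, known for its part in the repression of microRNA genes in the embryo. Its positions on chromatin were mapped by ChIP-seq through a GFP tag in mixed-stage embryos, in 2 biological replicates of 1 group. The optimal IDR set held 371 peaks, of which 364 lay on nuclear chromosomes and 7 on mitochondrial DNA. They were exactly the 371 entries with the highest signal value in the pooled list of 30000, with signal values from 90.3 to 1065 and a median of 127. It follows that no stronger pooled entry lay outside the set, and that the strongest 371 pooled entries are the same peaks. Membership does not show that a peak was found in both replicates: 349 of the 371 had an entry within 100 bp in both. Read depth is unknown.

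The first question was which sites the replicates shared. The strongest nuclear sites, led by snoRNA loci on chromosomes II and V, stood near the top of both lists: the peak at the snoRNA gene W03C9.9 ranked at 5 in replicate 1 and 3 in replicate 2, and that at T03F7.8 at 8 and 10. The peaks in the promoters of K12H4.5 and ftt-2 ranked at 18 and 16, and at 15 and 41. Among the 371 strongest entries of each replicate, 59.3% had a partner within 100 bp in the other, against a mean of 0.339% for shifted lists (one-sided permutation p = 0.001, the smallest possible with 1000 shifts). The shared part was 70.3% for the strongest 185 entries and 41.6% for the strongest 742. Of the 364 nuclear optimal peaks, 214 (58.8%, exact 95% interval 53.5 to 63.9) were among the strongest 371 entries in both replicates, 83 in replicate 1 alone, 49 in replicate 2 alone and 18 in neither. Across the 345 nuclear peaks matched in both lists, log2 signal values correlated with a Pearson r of 0.674 and a Spearman rho of 0.625 (permutation p = 1.0e-05 for each, the smallest possible), and r was 0.649 without the 2 peaks farthest from the median. This describes peaks, which are not independent replicates and had been selected on their pooled signal.

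**Figure D1:**
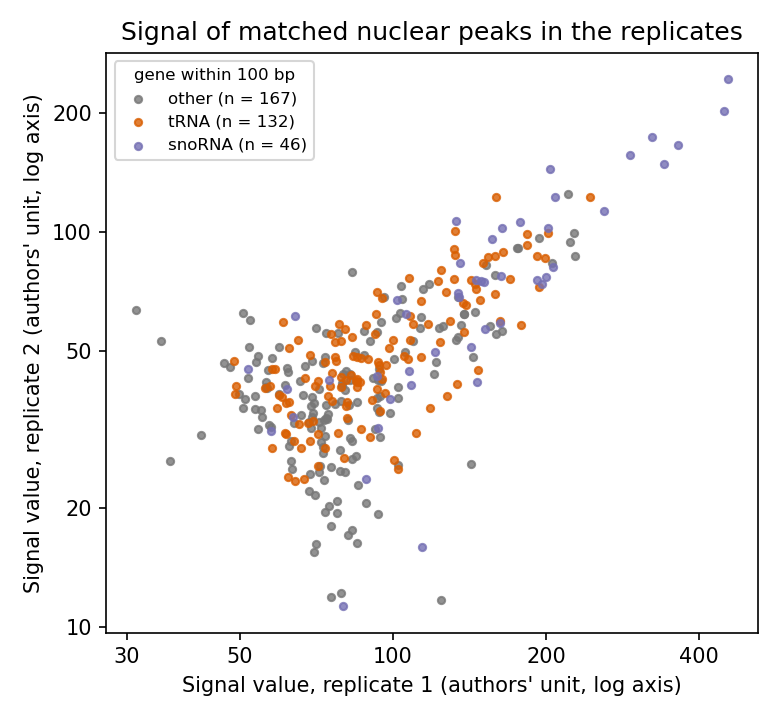
Signal values, in the authors' unit, of the 345 nuclear optimal peaks matched within 100 bp in both replicates, with replicate 1 on the horizontal and replicate 2 on the vertical log axis. Each point is a peak, coloured by the gene within 100 bp of the summit; peaks at snoRNA genes fill the upper right corner, and the Pearson r of the log2 values is 0.674.

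The second question was which genes lay at the peaks. Genes for small structural RNAs dominated: 158 of 612 nuclear tRNA genes had a summit from 1000 bp upstream to 200 bp downstream of their 5′ end, where background draws gave a mean of 5.25, and 53 of 346 snoRNA genes did, where draws gave 2.45. Genes for snRNAs, the RNAs of splicing, were also bound more often than in the draws, with 8 of 129 against 0.609, and 4 of them were the SL2 spliced leader genes sls-2.1, sls-2.2, sls-2.4 and sls-2.9. The list also counts sup-39 and the overlapping mir-1831, which share 1 peak. Each of these lists had an adjusted permutation p of 5.3e-04. The snRNA list did not pass in the strongest 185 peaks, where 2 genes remained (adjusted permutation p = 0.260), and with replicate 2 alone it counted 4 (adjusted permutation p = 0.0491). None of the 20 rRNA genes (draws 0.0095) or the 5 heterochronic microRNAs (draws 0.0876) was bound, nor did the 15363 piRNA genes (15 bound, draws 19.2) or the 194 long non-coding RNA genes (2 bound, draws 0.848) differ from the draws, with adjusted permutation p of 0.975 and 0.671. Against uniform random positions, which gave a mean of 59.7 bound piRNA genes, the 15 were fewer than expected (adjusted permutation p = 0.0032).

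Counted by distance, 138 of the 364 nuclear summits (37.9%, exact 95% interval 32.9 to 43.1) lay within 100 bp of a tRNA gene, against 0.799% in the background draws, and 47 (12.9%, 9.64 to 16.8) within 100 bp of a snoRNA gene, against 0.243% (permutation p = 2.0e-04 for each). No summit belonged to both groups. The snoRNA sites were the stronger ones, with a median signal value of 217, compared with 131 at tRNA genes and 112 at peaks near none of the small RNA genes. The 20 strongest optimal peaks of the genome comprised 6 on mitochondrial DNA, 10 at snoRNA genes, 1 at a tRNA gene and 3 near none of these, upstream of K12H4.5, mir-51 and ftt-2. Of the 10 strongest nuclear peaks, 8 were at snoRNA genes and 1 at a tRNA gene. Tied to this, 71.4% of the 91 strongest and 34.1% of the 91 weakest nuclear peaks were at tRNA or snoRNA genes (Fisher's exact p = 7.25e-07).

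The individual sites showed the same arrangement. The strongest nuclear peak (II, 11960635 to 11960989, signal value 695) was intergenic and had its summit 84 bp upstream of W03C9.9, as its offset of -84 bp records. The peak at V, 12303466 to 12303832 (signal value 653) lay in an intron of frm-7 at the snoRNA gene C51F7.4, and the peak at V, 11314038 to 11314384 (signal value 528) in an intron of cutl-18 at T03F7.8. The strongest tRNA site (X, 13665461 to 13665732, signal value 371) was at the leucine tRNA gene C04A11.t1, followed by the alanine tRNA gene F15G9.t1 in an intron of him-4 (X, 9743473 to 9743667, signal value 296). At tRNA genes 88 of 138 summits were inside the gene, whereas at snoRNA genes 43 of 47 (91.5%, exact interval 79.6 to 97.6) were upstream, 3 inside and 1 downstream, with a median offset of -43 bp from the 5′ end. No tRNA isotype stood apart in the share of genes with a summit within 100 bp: over 22 groups, 21 isotypes and 1 group of 5 genes with no isotype named, the lowest unadjusted Fisher's exact p was 0.0975, for alanine (12 of 34 genes), and every adjusted p was 1.

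**Figure D2:**
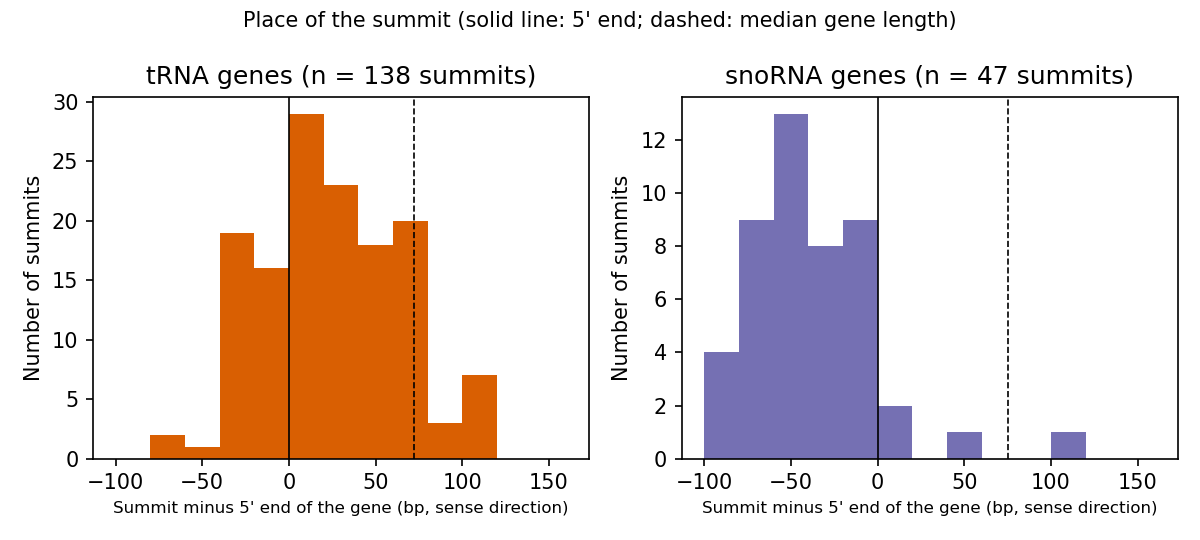
Distance in bp from the annotated 5′ end of the gene to the summit, in the direction of transcription, for 138 summits at tRNA genes and 47 at snoRNA genes; bars give the number of summits in bins of 20 bp. The solid line marks the 5′ end and the dashed line the median gene length; snoRNA summits lie mostly left of the solid line, with a median of -43 bp, and tRNA summits mostly to its right, with a median of 20.5 bp.

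Promoters of protein-coding genes were the other main location. Summits lay in a promoter in 146 of 364 cases (40.1%, exact 95% interval 35.0 to 45.3), compared with 23.6% in the draws (permutation p = 2.0e-04). Among the 179 peaks away from tRNA and snoRNA genes the share was 59.8%. Coding exons held 4 summits (1.10%), far below the 22.2% of the draws (permutation p = 2.0e-04), while introns held 114 (31.3%, draws 29.9%, permutation p = 0.563). With a single replicate the share in coding exons was 2.74% or 3.33%. Intergenic summits were more frequent than in the draws (95, 26.1% against 21.1%) and 3′ UTR summits less frequent (3, 0.824% against 2.62%), each with an adjusted permutation p of 0.0432. Neither call held against uniform positions or without the peaks at tRNA and snoRNA genes, and the intergenic one also ended with either replicate alone (adjusted permutation p = 0.129 and 0.172) and in the strongest 185 peaks. Without the peaks at tRNA and snoRNA genes, introns held fewer summits than the draws (16.8% against 30.4%, adjusted permutation p = 4.0e-04). Strength made no detectable difference, since 36.3% of the 91 strongest and 40.7% of the 91 weakest peaks were in promoters (Fisher's exact p = 0.648). The small difference changed sign with a promoter reaching 500 bp upstream and with replicate 1 alone.

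**Figure D3:**
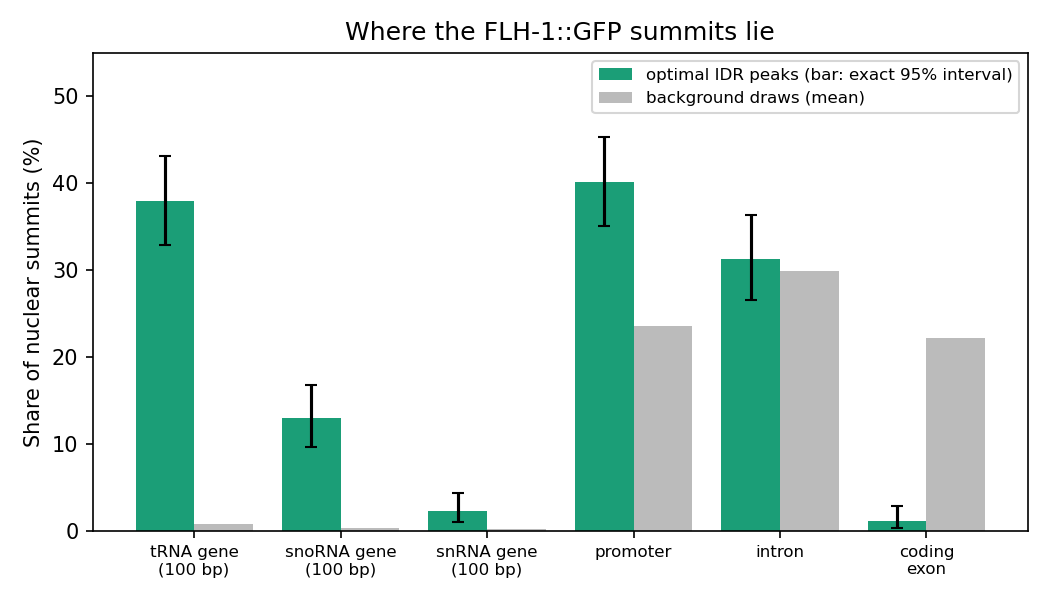
Share of nuclear summits, in percent, within 100 bp of a tRNA, snoRNA or snRNA gene, and in promoters, introns and coding exons of protein-coding genes. Green bars are the 364 optimal peaks with exact 95% intervals and grey bars the mean of the background draws; the gene classes and the locations overlap, and the tRNA bar stands at 37.9% against 0.799%.

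In all, 184 of 19973 protein-coding genes (0.921%) were bound. Without the peaks at tRNA and snoRNA genes, 140 were. Ribosomal protein genes were the only one of the 27 fixed protein-coding lists past the threshold: rpl-3 (signal value 199), rpl-15 (147), rps-28 (133), rpl-35 (123) and rps-3A (111), 5 of 78 genes, had a summit upstream of the gene, compared with 0.900% of other genes (odds ratio 7.54, Fisher's exact p = 7.70e-04, adjusted p = 0.0208). None of these 5 peaks was at a tRNA or snoRNA gene. The call did not hold against background draws in place of Fisher's test (mean 0.753, adjusted permutation p = 0.0810) or in the strongest 185 peaks, where 3 genes were bound (odds ratio 8.71, adjusted exact p = 0.161). The excess itself stayed in both settings.

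Other lists did not pass after adjustment. Histone genes had 3 of 72 bound (his-67 and his-68, which share 1 peak, and his-72; adjusted exact p = 0.195). Among heat shock genes the chaperone genes hsp-1 and hsp-60 were bound, 2 of 24 (adjusted exact p = 0.184), and among translation factors eif-3.C and eif-2Bgamma, 2 of 33 (adjusted exact p = 0.200). Chemoreceptor genes had 4 of 1285 (sre-23, sre-1, srh-269 and sri-5; odds ratio 0.321, adjusted exact p = 0.184). Background draws gave them a mean of 2.08, so against scored positions the 4 were not fewer. Single genes were bound in the lists of Wnt signalling (mom-1), maternal and germline genes (mex-1), bHLH factors (hlh-11), proteasome (rpn-7), nuclear hormone receptors (nhr-255), collagens (col-185), F-box genes (fbxb-85) and C-type lectins (clec-126). The peaks counted for mom-1, nhr-255, col-185, clec-126, srh-269 and sre-23 were themselves at tRNA or snoRNA genes. That for eif-2Bgamma was the peak at sup-39, listed among the snRNA genes, which was also counted for mir-1831. The remaining 14 lists, with 247 entries, had no bound gene: FLYWCH family, heterochronic genes, body wall muscle, intestine, pharynx, epidermis, neuron, Hox, Notch signalling, cell cycle, synMuv B, dosage compensation, ceh homeobox and T-box. Background draws gave each of these lists a mean from 0.0447 to 0.548 bound genes, so finding none does not set them apart.

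MicroRNA genes were of interest because lin-4, mir-48 and mir-241, timing regulators of larval development, are known to be repressed by FLH-1 and FLH-2 in embryos. None of these had an optimal peak. The strongest entry at lin-4 or up to 2000 bp upstream ranked at 655 in replicate 1, 10341 in replicate 2 and 1215 in the pooled list, where its signal value of 61.7 lay below the weakest optimal peak at 90.3. The strongest pooled entries at mir-48 and mir-241 ranked at 26748 and 9760, and those at let-7 and mir-84, from the same class of timing microRNAs, at 17013 and 7125. Of all 262 microRNA genes 5 had a summit from 1000 bp upstream to 200 bp downstream of their 5′ end, against 2.06 in the draws (adjusted permutation p = 0.388). They were mir-51 (signal value 329, IV, 11026054 to 11026343), mir-52 (300, IV, 14033876 to 14034211), mir-90 (111), mir-1831 (104.2) and mir-4936 (103.5). With replicate 1 alone the number was 9 (adjusted permutation p = 0.0300), and with replicate 2 alone 8 (adjusted permutation p = 0.0572).

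Genes carried as extra copies by the tagged strain and genes for related proteins were examined next. At flh-1 itself (IV, 9261807 to 9264270) and at flh-3 (IV, 9270096 to 9271938) no list had an entry inside the gene or up to 2000 bp upstream. The strongest pooled entries at unc-119 and flh-2 ranked at 6236 and 11314. At peb-1, which codes for another FLYWCH protein, the strongest entry ranked at 2154 in replicate 1, 306 in replicate 2 and 576 in the pooled list, with a signal value of 76.0, so it too was below the optimal set.

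Chromosome X held more peaks than the background. It had 95 of the 364 nuclear peaks (26.1%, exact 95% interval 21.7 to 30.9) against 16.3% of background summits (exact binomial test, adjusted p = 1.41e-05), and chromosome V held fewer, 42 (11.5% against 18.4%, adjusted exact p = 0.00127); the latter call did not hold in the strongest 185 peaks (11.8% against 18.3%, adjusted exact p = 0.0761). Peaks at tRNA genes were on X in 61 of 138 cases (44.2%), and X carries 276 of the 612 tRNA genes, whereas none of the 47 peaks at snoRNA genes was on X. tRNA genes on X had a summit within 100 bp about as often as those on autosomes, 64 of 276 (23.2%) and 79 of 336 (23.5%; Fisher's exact p = 1). Without the peaks at tRNA and snoRNA genes, X held 34 of 179 (18.99%), which did not differ from its background (adjusted exact p = 0.729), and chromosome III held 46 (25.7% against 16.4%, adjusted exact p = 0.00967). Over all peaks chromosome III did not differ (18.96%, adjusted exact p = 0.283), except with replicate 1 alone or against uniform positions (adjusted exact p = 0.0388 and 0.0119).

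**Figure D4:**
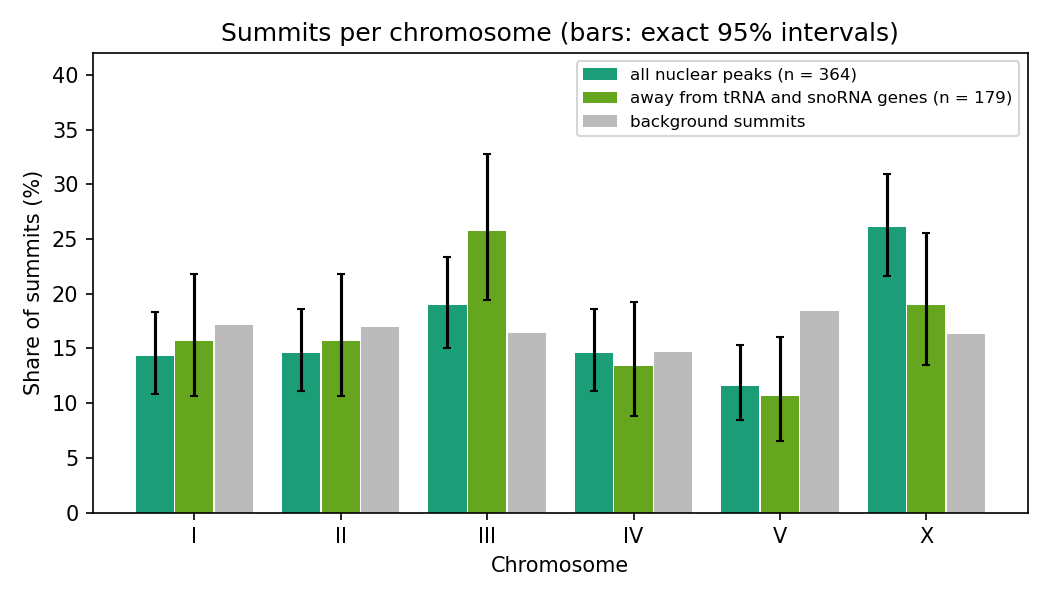
Share of summits, in percent, on each nuclear chromosome for all 364 nuclear peaks, for the 179 peaks away from tRNA and snoRNA genes, and for the background summits; error bars are exact 95% intervals. On X the share is 26.1% for all peaks and 18.99% for the peaks away from these genes, against 16.3% of the background.

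Sequence at the summits was rich in G and C, with a mean GC content of 51.1% (SD 7.62 over 364 peaks) compared with 41.1% in the draws (permutation p = 2.0e-04). It was 55.2% at snoRNA peaks and 50.2% at tRNA peaks. On chromosomes I, III and V, 68 words of 6 bp were more frequent than in matched background summits, led by GTTCGA, TTGCAA, GCGCGC, CGAACC and ACCACT. On II, IV and X, GTTCGA stood in 28.4% of peaks against 3.79% of the background (Fisher's exact adjusted p = 1.08e-26), CGAACC in 23.9% against 3.79% (adjusted exact p = 3.34e-20) and ACCACT in 22.4% against 5.08% (adjusted exact p = 1.49e-14). GTTCGA is part of the B box, the internal promoter element of tRNA genes. TTGCAA (3.98% against 2.67%, adjusted exact p = 0.262) and GCGCGC (6.97% against 3.90%, adjusted exact p = 0.0759) did not pass there. With replicate 2 alone the share of TTGCAA was 6.63% (adjusted exact p = 0.0841). Both words passed in the widest window (11.4% each, adjusted exact p = 0.0319 and 0.00178), and GCGCGC also with replicate 1 alone (adjusted exact p = 0.0291) and against the peaks' own flanks (adjusted exact p = 1.4e-04). The enrichment of GTTCGA, CGAACC and ACCACT ended without the peaks at tRNA and snoRNA genes (5.81%, 4.65% and 5.81%, each with an adjusted exact p of 1), while GCGCGC then passed (13.95%, adjusted exact p = 0.00180). Of the 9 words fixed in advance 1 passed: CAGCTG was in 1.10% of peaks against 3.80% of the background (adjusted exact p = 0.0394). This call did not hold in the strongest 185 peaks, with either replicate alone, without the peaks at tRNA and snoRNA genes, in a narrower or wider window, or against the peaks' own flanks (adjusted exact p from 0.0655 to 0.550), though CAGCTG stayed below its background each time; its share was 2.47% with replicate 1 alone and 2.22% with replicate 2 alone. Conversely, GGGCGG (11.8% against 8.03%, adjusted exact p = 0.0758) passed with replicate 1 alone, in the widest window and against the flanks (adjusted exact p from 1.4e-11 to 0.00606), and GAGAGA (14.6% against 12.1%, adjusted exact p = 0.406) in the last 2 of these (adjusted exact p = 4.97e-04 and 0.00253), both as enriched. Calls gained in 1 or 2 settings were also seen for TGATAA, as depleted against the flanks (3.57% against 10.9%, adjusted exact p = 7.23e-05), and for ATTTTT, as enriched in the widest window (adjusted exact p = 0.0357) but depleted against the flanks (adjusted exact p = 2.05e-18), and for GGCGCC and TGCGTC, as enriched against the flanks (adjusted exact p = 0.0413 and 8.05e-04). The flanks were not matched on GC content, and ATTTTT stood in 46.2% of them but in 15.6% of the matched background. Calls against the flanks therefore cannot be told apart from a difference in base composition.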

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

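The test on mitochondrial DNA was chosen after the replicate ranks had been seen, and the comparison of highly transcribed genes with snoRNA genes had no written prediction. The other tests reported in this part were written down before their values were computed, though the patterns themselves had been seen.

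Signal on mitochondrial DNA lies outside the location tests, and 7 optimal peaks are there, including the 3 strongest of all, with signal values of 1065, 934 and 847. Of these 7, 4 had an entry within 100 bp in both replicates. These 4 include the 3 strongest and ranked from 1 to 7 in replicate 1 and from 2 to 15 in replicate 2. They thus do not rest on 1 replicate, while each of the others lacked an entry within 100 bp in 1 of them. Among these others, the peak at 4956 to 5419 overlaps the strongest peak, at 4756 to 5219, which had an entry in both replicates. The 100 bp limit can therefore lower the count of 4. For the 7 as a set, 4 is too few to exclude and too many to support a difference between replicates in mitochondrial reads as the source. Such a difference cannot be told apart from a shared property of mitochondrial DNA. No biological explanation was tested.

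The peaks at tRNA and snoRNA genes are the main pattern of the nuclear data. Reads shared between identical gene copies are argued against at the summit itself for most of these peaks. The 51 bp at the summit occur once in the genome for 78.3% of the 138 tRNA peaks (exact 95% interval 70.4 to 84.8) and for 100% of the 47 snoRNA peaks (from 92.5). At the other tRNA peaks those 51 bp occurred up to 33 times, so the explanation stays open there. Only exact matches of the 51 bp were counted, so copies that differ in any base pass as unique. Summits were upstream of the gene at 43 of 47 snoRNA and 38 of 138 tRNA peaks, so their windows take in flanking sequence. Sharing of reads elsewhere under a peak, or between near-identical copies, was therefore not tested. The aligner is unknown, and so is its treatment of reads that fit several places. A general pull toward highly transcribed genes is also argued against as the whole cause at tRNA genes, as far as ribosomal protein and histone genes stand in for high transcription. Of these 150 genes, 5.33% had a summit, with an upper bound of 10.2%, below the lower bound of 20.1% for tRNA genes. For snoRNA genes the lower bound was 10.4%, a margin too narrow to decide, and no prediction had been written for them. The protein-coding genes were counted in the wider promoter window, which leaves out most of the gene body. Small RNA genes were counted over the whole gene and 100 bp to each side, so which side this difference favours is not known. In the same window as the protein-coding genes, 25.8% of tRNA genes and 15.3% of snoRNA genes had a summit. The 5.33% itself lay above the 0.921% of all protein-coding genes, so a partial pull stays open. Ribosomal protein genes were bound more often than other genes by Fisher's exact test (odds ratio 7.54). That call did not hold against background draws (5 genes against a mean of 0.753) or in the strongest 185 peaks (odds ratio 8.71), though the excess stayed in both. Transcription was not measured here. What stays open is whether FLH-1 itself is at these genes or whether their chromatin is recovered with any tagged protein, because no mock precipitation was analysed. Of biological explanations, only the promoter type of the snoRNA genes at these peaks was tested, as given under Other observations.

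The excess of peaks on X goes with the place of tRNA genes. Among the 226 peaks with no tRNA gene within 100 bp, 15.04% were on X (exact 95% interval 10.6 to 20.4), an interval that holds the background share of 16.3%. X makes up 17.7% of the nuclear genome, below the lower bound of 21.7% for the peaks, which argues against chromosome length as the source. This value does not test a larger share of scored positions on X. The excess had already been measured against scored positions, the background summits, of which X held 16.3%.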

How the results depend on the processing

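Results without the peaks at tRNA and snoRNA genes, those on nuclear entries only and all alternatives for peaks at these genes were chosen after seeing the data. For results with a test, 44 of 48 alternatives kept the direction and the side of the threshold. For counts, 29 of 41 alternatives stayed within 1.5 times the main count. Single chromosomes, locations, gene lists and words past the threshold in any setting, a choice made after seeing the data, had 208 alternatives, of which 18 gained a call, 21 lost it, 18 changed direction and the rest kept direction and side. Promoter share (29.4% to 59.8%), GC content (50.4% to 51.8%), replicate agreement (41.6% to 70.3%) and the peaks at tRNA (24.2% to 43.8%) and snoRNA genes (0.824% to 21.3%) did so under every alternative run; the lowest snoRNA value counts only summits inside the gene. The top 371 pooled entries are the optimal peaks, so that setting, and the search for strong entries outside the set, could not change anything. The tallies above include these alternatives, whose agreement was fixed in advance.

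The strongest 185 peaks, of which 178 were nuclear and entered these tests, are a smaller set by construction. They gave 94 bound protein-coding genes, 0 protein-coding lists and 23 enriched words. Without the peaks at tRNA and snoRNA genes, the X share was 18.99%, the shares in introns and intergenic sequence fell to 16.8% and 19.6%, below their background (introns also at 25.8% with a promoter of 2000 bp), 1 non-coding list passed, 27 words were enriched, the promoter share of the strongest minus the weakest peaks turned to 2.27 percentage points, and CGAACC fell to 4.65%, below its background. That difference by strength was -4.40 at first, 2.20 with a promoter of 500 bp, and ranged from -7.78 to 1.10 with a replicate left out; none of these passed its exact test. With a replicate left out, 1 to 2 protein-coding lists (without replicate 1, chemoreceptor genes were also past the threshold, as bound less often) and 42 to 48 words passed. Background draws in place of Fisher's test gave 0 protein-coding lists, and over all peaks the 4 bound chemoreceptor genes lay above their mean of 2.08. Enriched words numbered 23 in the 51 bp window, 103 in the widest window and 172 against the peaks' own flanks, where TTGCAA (3.98%) fell below its background. CAGCTG lost its call in every setting that could change it, and chromosome V in the strongest 185 peaks. Other words fixed in advance changed direction: GGCGCC without the peaks at tRNA and snoRNA genes (3.35%), in the 51 bp window (2.20%) and against the flanks (3.02%), TGCGTC without those peaks (7.82%), in the widest window (11.54%) and against the flanks (5.49%), and ATTTTT against the flanks (18.96%). With a replicate left out, GGCGCC ranged from 2.47% to 3.33%, TGATAA from 3.29% to 4.44%, TGCGTC from 6.58% to 7.50%, ATTTTT from 17.2% to 19.2%, and bound piRNA genes from 9 to 22; each changed direction with 1 replicate alone, and TGCGTC with both. Of these changes, those of GGCGCC, TGCGTC and ATTTTT against the flanks passed. Apart from the smaller set, the cause of these changes was not tested, and those against the flanks cannot be told apart from a difference in base composition. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on the weaker entries, such as that at lin-4, could not be assessed.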

Other observations

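Away from tRNA and snoRNA genes, the leading words differed in part. GCGCGC and TTGCAA had also been named from all peaks. The GCGCGC test repeats the one given under Results, adjusted here with other words. GCGCGC and CGCGCG overlap, as do TTGCAA and CTTGCA, so these are not separate findings. Named on chromosomes I, III and V from these peaks and tested on the 86 of them on II, IV and X, in tests chosen after seeing the data, CGCACA stood in 23.3% against 6.11% of matched background summits (Fisher's exact adjusted p = 7.36e-06), GCGCGC in 13.95% against 3.83% (adjusted exact p = 8.98e-04), CGCGCG in 11.6% against 3.95% and CTTGCA in 10.5% against 3.35% (adjusted exact p = 0.00619 for both). TTGCAA was in 6.98% against 2.87% and did not pass (adjusted exact p = 0.0528). Among the strongest peaks away from these genes were those in the promoters of ears-2 (signal value 289), atx-2 (288) and idhg-1 (270), named after their values were seen.

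A hypothesis on the snoRNA sites was tested with a prediction written before its value was computed. In C. elegans some snoRNA genes have promoters of RNA polymerase III, the polymerase of tRNA genes. If the snoRNA genes with a summit within 100 bp are of that kind, they should carry the B box core on the sense strand more often than the others. Within 150 bp of the gene, 26 of the 48 snoRNA genes with such a summit (54.2%) had it, compared with 29 of 298 others (9.73%), an odds ratio of 10.96 (95% interval 5.21 to 22.96, Fisher's exact p = 1.25e-11). On the antisense strand it was 6.25% and 5.37% (Fisher's exact p = 0.736). The strand-specific excess is consistent with a shared property of tRNA genes and these snoRNA genes, which may be their polymerase, and no polymerase III data were analysed here. The genes with such a summit but without the core are left unexplained.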
